A study of Drosophila melanogaster with 2 samples.

How the data were processed

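Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out with an antibody against GFP on whole Drosophila melanogaster embryos collected 0 to 24 h after egg laying, from a transgenic line in which the transcription factor Gcm2 (glial cells missing 2) carries GFP at its C terminus. The 2 libraries, labelled biological replicates 2 and 3, form 1 group, and chromatin was sonicated to 200 to 800 bp, per the labels. No mock or untagged library was analysed here, so no comparison between conditions was made and every statement compares regions within these libraries.

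Per the file lists deposited with the samples, the authors made each replicate's candidate list from that replicate's alignments and a control file. The pooled list came from the alignments of both replicates. The final list came from the 3 candidate lists by the irreproducible discovery rate (IDR), which is based on how alike regions rank in both replicates. In dm6 this final list was the 2177 strongest pooled candidates by signal, so a kept region need not rank alike in both replicates. At 63.8% of IDR summits, both replicates had a region from their own 2177 strongest, and at 93.9% both had a candidate. The aligner, the peak caller, its version and the IDR threshold are not given in the sources used here. There are 8 lists, 4 in each of 2 genome builds (dm6 and dm3), and each candidate list holds 30000 regions, background regions included. The signal value of each region is the authors' own enrichment value, with no replicate error, and was used only to describe, rank or filter regions within a list. The deposited −log10 q-value of each region is also the authors', and the summit offset gave the position of the strongest point of each region. Read depth is unknown, so no depth could be set beside the values, and intervals cover counting error only.

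The dm6 lists were compared with the Release 6 reference sequence and the Ensembl 115 annotation, after checking that the largest region end on each chromosome lay within the reference length; the dm3 lists were described by counts alone. Coordinates are 1-based in dm6. Each summit was classed, in order, as promoter (within 500 bp of an annotated transcription start site, TSS), coding exon, 5' UTR, 3' UTR, other exon, intron or intergenic. IDR peaks were compared with weak candidates, the 27135 pooled candidates overlapping no IDR peak, since these were also put to the authors' threshold. Most weak candidates had a q-value above 0.05: of all 30000 pooled candidates, IDR peaks included, 6821 had one at or below it. Another 688 candidates overlapped an IDR peak and were left out.

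Shares were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment within each family of 7 annotation classes, 6 chromosomes, 12 motifs or 21 gene lists and a threshold of 0.05. Motifs were searched as consensus sequences on both strands within 100 bp of the summit. For gene lists, a protein-coding gene counted when an IDR summit lay within 1 kb of a TSS, and the list was set against all other protein-coding genes. The strongest 2177 regions of each replicate's own list, as many as there are IDR peaks, gave the spread between libraries (mean ± SD, n = 2). Replicates were compared by the share of those regions with summits within 100 bp, against 10000 draws of as many random regions from replicate 3 (one-sided permutation test). Shares carry 95% Wilson intervals. For a count of 0 the limit given is 3 counts of the total, which differs from the Wilson upper bound drawn in the plot of gene lists, and both are printed.

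The tests, motifs, gene lists and most alternative settings were fixed before the data were examined, and settings added later are named as such. So was the rule for naming genes: gcm2 and gcm always, the genes nearest the 15 strongest IDR peaks, every member of the Gcm pathway, glia and hemocyte lists with an IDR summit within 1 kb, and up to 3 members of each other list by signal. The lists were Gcm pathway targets, glia, hemocyte, neuron, neuroblast and proneural, muscle and tendon, trachea, epidermis and septate junction, germline, Hox, segmentation, Notch, EGFR and FGF, Wnt and Hedgehog, JAK/STAT, cytosolic ribosomal protein, mitochondrial ribosomal protein, proteasome, cuticle protein, odorant and gustatory receptor, and cytochrome P450. Several were drawn up by symbol prefix, so the ribosomal list holds 5 symbols containing "like" and the cuticle list holds the gene Cpr, which is not a cuticle protein.

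Alternatives changed the overlap that counts as shared, the number of regions, the replicate used, the promoter and TSS distances, the motif window and the background. Matching on GC content was first done by drawing 5 weak candidates per IDR peak at random. Repeated draws gave different values, so that setting was replaced, after its values had been seen, by a Mantel-Haenszel odds ratio over 24 bins of GC content that uses all weak candidates, with a permutation test of 100000 draws within bins. A restriction to chromosomes 2L, 2R, 3L, 3R, 4 and X removed no region.

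The functions were tested on simulated data. For the motif comparison, 100% of planted matches in 2177 simulated windows were found, and 0 of 20 sets with nothing planted gave a call. Both simulated sets had the same base composition, whereas mean GC content was 38.1% at IDR peaks and 44.8% at weak candidates. The simulation therefore does not cover calls that arise from a difference in GC content. For the annotation comparison, 100% of planted promoter positions were classed as promoter. For the gene lists, with 13968 genes, a planted ribosomal list was called in 99 of 100 sets, while 0 of 100 unplanted sets gave a call. With 3 of the 6 Gcm pathway genes planted, that list was called in 0 of 100 sets. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.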

Results

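Binding of GFP-tagged Gcm2, a zinc-containing transcription factor that acts with its paralog Gcm in glial and blood cell development of the fly, was mapped by ChIP-seq in whole embryos. The data are lists of candidate regions for 2 biological replicates, for both pooled, and a list of regions retained by IDR. In dm6 the IDR list held 2177 peaks and each candidate list 30000 regions.

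The first question was which regions the authors' threshold retained. The IDR peaks were the 2177 strongest of the 30000 pooled candidates by signal (7.26%), with signal from 57.8 to 1029 and a median of 82.4. The median of the remaining candidates was 19.8, a 4.16-fold difference. The strongest peak (2L:480890-481290) lay in an intron of ush, which encodes a GATA cofactor, and its nearest protein-coding TSS was that of cbt, a zinc finger factor, 1365 bp away. It ranked 1 in both replicates, with signal 527 in replicate 2 and 475 in replicate 3. All IDR peaks had the smallest q-value in the list (1.63e-04), which 887 other candidates shared. The dm3 lists held 2459 IDR peaks, again the strongest of 30000 candidates (8.20%).

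The genes nearest the next strongest peaks were CG14100 (3L:19590432-19590814, signal 768), the UDP-galactose transporter gene Ugalt (X:2703689-2704076, signal 689), CG11050 (2L:6612509-6612904, signal 646) and Chro, which encodes a chromatin protein (3L:22878724-22879107, signal 618). Those of CG14100, Ugalt and Chro were promoter peaks, and that of CG11050 lay in an intron of the gene. The other genes nearest the 15 strongest peaks were px, Lk6, CG4004, CG1888, CG9663, CG31145, CG13323, ph-p, hll and PNPase. Of the 15 peaks, 9 were at promoters, 4 in introns, 1 in another exon and 1 between genes. Their lowest rank was 18 in replicate 2 and 17 in replicate 3. Only the peak in an intron of CG9663 (2L:3301989-3302326, signal 522) had a GCM octamer within 100 bp.

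The second question was how far the replicates gave the same regions. Of the 2177 strongest regions of replicate 2, 1381 (63.4%) had a summit within 100 bp of one of the 2177 strongest of replicate 3. Random draws from replicate 3 shared 6.45% on average and 8.77% at most (one-sided permutation test, p = 0.0001, the smallest the draws can give). By a looser rule, summits within 250 bp, 489 of the 500 strongest regions of replicate 2 matched the 2177 strongest of replicate 3. By that rule 493 of the 500 strongest of replicate 3 matched the 2177 strongest of replicate 2. At 2045 IDR peaks (93.9%) both replicates had a candidate summit within 100 bp, and the ranks there correlated with a Spearman rho of 0.62 across peaks, which are not independent replicates. The shared percentage was 51.4% within 50 bp and 70.5% for any overlap of the regions.

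The third question was where in the genome the peaks lay. IDR peaks lay at promoters more often than weak candidates did: 1256 of 2177 (57.7%, interval 55.6 to 59.8) against 30.3%. Replicates' own strongest regions gave 58.2% ± 0.227 (SD, n = 2). Coding exons held 5 IDR summits (0.230%) against 18.1% of weak candidates. The median distance to a TSS was 307 bp for IDR peaks and 1225 bp for weak candidates. By Fisher's exact test, two-sided, the odds ratio was 3.14 for promoters (adjusted p = 5.4e-141) and 0.010 for coding exons (adjusted p = 7.6e-170; 0.0157 without replicate 3 and 0.0174 without replicate 2). Introns (30.04% against 33.9%, adjusted p = 2.7e-04), intergenic sequence (9.88% against 13.1%, adjusted p = 1.9e-05), 3' UTRs (0.689% against 2.71%, adjusted p = 1.0e-10) and 5' UTRs (0.459% against 0.899%, adjusted p = 0.035) had lower shares by the same exact test. Each summit had 1 class and promoters were assigned first, so the larger promoter share lowers the other shares. Of summits over 500 bp from a TSS, introns held 654 of 921 at IDR peaks and 9211 of 18915 at weak candidates. Intergenic sequence held 215 and 3547 of these, so both shares were larger at IDR peaks there (not tested). Coding exons and both UTR classes remained less frequent there. The 5' UTR call held in only 1 of 7 alternative settings (promoters of 250 bp) and was lost without replicate 2 (odds ratio 0.59) and without replicate 3 (0.76), the 3' UTR odds ratio of 0.25 became 0.14 and 0.16 in the same order, and the intron (0.97) and intergenic (0.94) calls were lost with promoters of 250 bp. Other exons did not pass (1.01% against 0.943%, Fisher's exact test, adjusted p = 0.73). Against only the candidates ranked just below the IDR peaks, a background added after the data were seen, promoters (odds ratio 1.24) and coding exons (odds ratio 0.123) still passed, far closer to 1, and the other 4 classes did not.

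**Figure D1:**
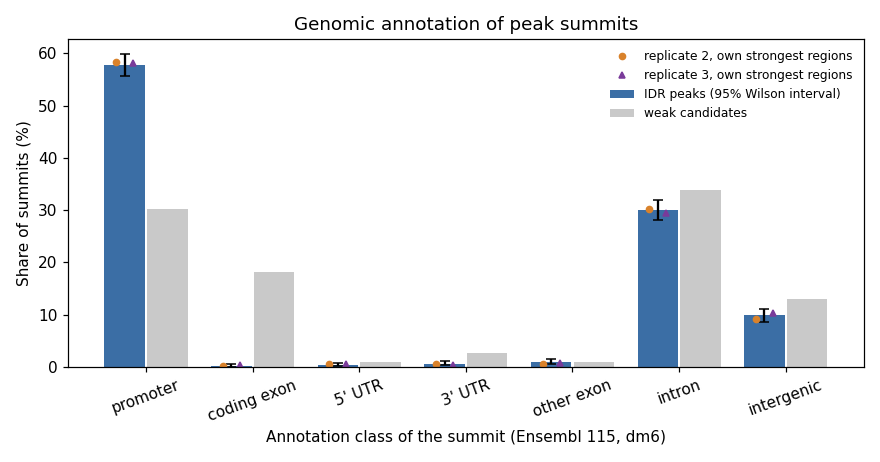
Share of summits (%) in each annotation class for the 2177 IDR peaks (blue, with 95% Wilson intervals) and the 27135 weak candidates (grey); points give each replicate's own strongest regions. Promoters hold 57.7% of IDR peaks and 30.3% of weak candidates, and coding exons 0.230% and 18.1%.

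Chromosome 4 held 6 IDR peaks (0.276%) against 0.774% of weak candidates (Fisher's exact test, two-sided, odds ratio 0.35, adjusted p = 0.035). The X chromosome held 17.7% against 15.9%, which did not pass (Fisher's exact test, adjusted p = 0.094), and neither did 2L, 2R, 3L or 3R. However, X passed without replicate 3 (odds ratio 1.18), and X, 2L and 3R passed with the upper part of the IDR list by signal (1.20, 1.19 and 0.84). Set against its share of sequence length, X gave a ratio of 1.01 and did not pass. The chromosome 4 call was lost when the upper part of the IDR list by signal was used or replicate 2 was left out.

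The fourth question was whether the known GCM consensus, ATRCGGGY, marked the peaks. It did so less often at IDR peaks than at weak candidates: 17 of 2177 summits (0.781%, interval 0.488 to 1.25) had a match within 100 bp, against 1.59%. Replicates' own strongest regions gave 0.804% ± 0.162 (SD, n = 2). The odds ratio was 0.49 (Fisher's exact test, two-sided, adjusted p = 0.0033). The call was lost in 7 of 10 alternative settings, among them leaving out replicate 3 (odds ratio 0.66) and matching on GC content (odds ratio 0.77, permutation test, adjusted p = 0.42, and 0.0011 to 0.93 over the 10). The stricter octamer ATGCGGGT gave 0.322% against 0.483%, which did not pass (Fisher's exact test, adjusted p = 0.55). Of 100 random permutations of the consensus, 77 had an IDR to weak ratio at least as high as its 0.49. By distance from IDR summits, GCM matches numbered 45.9 per Mb within 50 bp (10 matches), 41.3 at 50 to 100 bp, 66.6 at 100 to 200 bp, 63.2 at 200 to 400 bp, 50.5 at 400 to 700 bp and 46.7 at 700 to 990 bp. At weak candidates the density fell from 86.6 per Mb within 50 bp through 76.7, 65.2, 63.7 and 55.9 to 55.7 per Mb over the same distances.

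Sites of several general promoter and architectural factors were more frequent at IDR peaks. The DRE octamer TATCGATA, bound by DREF, was found at 4.04% against 1.46% (Fisher's exact test, two-sided, odds ratio 2.84, adjusted p = 7.2e-14). The homeodomain core TAATTA (14.2% against 10.4%, odds ratio 1.44), the GAF site GAGAGAG (5.51% against 3.90%, odds ratio 1.44), the M1BP site GGTCACACT (1.93% against 1.02%, odds ratio 1.91) and the CTCF site AGGTGGCGC (0.873% against 0.369%, odds ratio 2.38) also passed. The Su(H) core (9.69% against 11.4%) and the Tramtrack site (1 peak, 0.0459%, against 0.457%) were less frequent. Zelda, the proneural E-box and GATA sites did not pass, but Zelda was less frequent without replicate 2 (odds ratio 0.58, Fisher's exact test, adjusted p = 0.036, 0.036 to 0.93 over its alternatives). The E-box (odds ratio 0.99) passed in both directions: it was more frequent when matched on GC content (1.42) or set against positions 1 kb away (1.26), and less frequent over 500 bp from a TSS (0.62). Mean GC content of the windows was 38.1% at IDR peaks and 44.8% at weak candidates. Matched on GC content, the homeodomain core turned to an odds ratio of 0.89 and did not pass, and the Tramtrack call was lost (0.29). Within 500 bp of a TSS, a setting added after the data were seen, only DRE (odds ratio 1.70) and the homeodomain core (1.41) passed, while GAF (1.19), M1BP (1.10), CTCF (1.88), Su(H) (0.90) and Tramtrack (0.23) did not. Over 500 bp from a TSS, DRE (1.01), GAF (1.26), M1BP (0.66), Su(H) (0.81) and Tramtrack (0 peaks) did not pass. The GAF (0.96), CTCF (1.23), Su(H) (0.85) and Tramtrack calls were lost in a 50 bp window, that of M1BP (1.36) with the upper part of the IDR list by signal, and those of CTCF (1.75) and Su(H) (0.85) without replicate 2. Leaving out replicate 2 raised the M1BP odds ratio to 3.02, and leaving out replicate 3 left 0 Tramtrack matches. Against the candidates just below the IDR peaks, also added later, no motif passed.

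**Figure D2:**
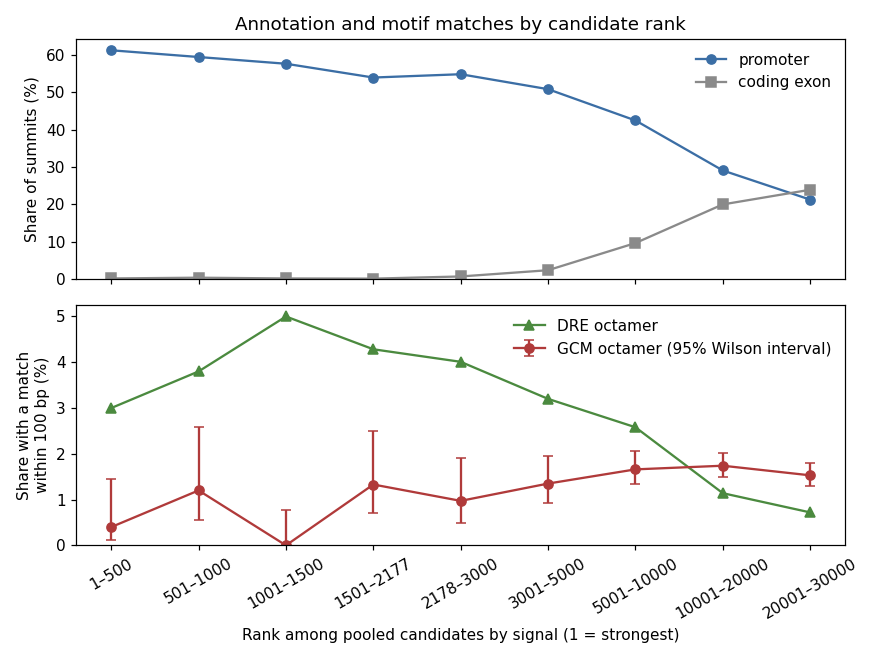
Share of summits (%) by rank of the pooled candidates, for promoters and coding exons (upper) and for GCM and DRE octamers within 100 bp (lower, GCM with 95% Wilson intervals). The promoter share falls from 61.2% in the 500 strongest to 21.3% in the weakest group, and the GCM share is 0.400% and 1.53% in the same groups.

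The fifth question was which genes lay near the peaks. Of 13968 protein-coding genes, 1766 (12.6%) had an IDR summit within 1 kb of a TSS. Genes of cytosolic ribosomal proteins stood out, with 57 of 92 (62.0%, interval 51.7 to 71.2; Fisher's exact test, two-sided, odds ratio 11.6, adjusted p = 2.0e-27). Among them were RpL7 (2L:10200882-10201160, signal 326), RpS27 (3R:25247408-25247674, signal 317) and RpS4 (3L:13041671-13041855, signal 212). Replicates' own strongest regions reached 57 and 52 of these genes.

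Smaller shares than among all other genes had a peak for cuticle protein genes (1 of 118, Cpr73D; Fisher's exact test, adjusted p = 2.9e-05), odorant and gustatory receptor genes (1 of 119, Or88a; Fisher's exact test, adjusted p = 2.8e-05) and cytochrome P450 genes (1 of 83, Cyp6u1; Fisher's exact test, adjusted p = 0.0018). The odds ratios were 0.059, 0.058 and 0.084. When only genes with any pooled candidate near a TSS were used as background, a setting added after the data were seen, they were 0.123, 0.207 and 0.119 and none passed. Leaving out replicate 2 gave 0.118 for cuticle protein genes. The P450 call was also lost with the upper part of the IDR list by signal (0.162).

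None of the 6 Gcm pathway genes had an IDR summit within 1 kb of a TSS, which allows a share of up to 50% (3 counts of the total; the Wilson upper bound is 39.0%) and did not pass (Fisher's exact test, two-sided, adjusted p = 1); 4 of the 6 would have been needed to pass. Each replicate's own strongest regions reached 1 of the 6, pnt, which gave odds ratios of 1.37 and 1.38. Their strongest candidates near a TSS ranked 2235 for pnt, 3128 for loco, 3176 for gcm2, 3634 for ttk, 7359 for repo and 12080 for gcm. The Ets factor gene pnt held 1 IDR summit inside the gene (3R:23326239-23326702, signal 131, rank 420). Among 23 glial genes, 3 had an IDR peak (13.04%, interval 4.54 to 32.1; odds ratio 1.04, Fisher's exact test, adjusted p = 1). These were Gs2, glutamine synthetase (X:11423321-11423465, signal 203), moody, a receptor of the blood-brain barrier (X:2050166-2050397, signal 174), and htl, an FGF receptor (3R:18049500-18049963, signal 60.4). Replicates' own strongest regions reached 4 glial genes each. The htl peak had no candidate within 100 bp in replicate 3, although htl was among the genes reached by the strongest regions of replicate 3 and not of replicate 2. Of the other list members named here, the peak of insc in replicate 3 and those of Socs36E and Rpn5 in replicate 2 also had none within 100 bp, and the strongest regions of those replicates reached only Rpn5. None of 23 hemocyte genes had an IDR summit within 1 kb of a TSS, which allows up to 13.04% (Wilson upper bound 14.3%; Fisher's exact test, adjusted p = 0.32). However, 2 of them held an IDR summit inside the gene, ush with the strongest of all IDR peaks and zfh1, both looked up after the values were seen (odds ratio 0.55 with gene bodies counted, not passing). Replicate 2's own strongest regions reached 1 hemocyte gene near a TSS, ush, and those of replicate 3 reached 0 (odds ratios 0.31 and 0).

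**Figure D3:**
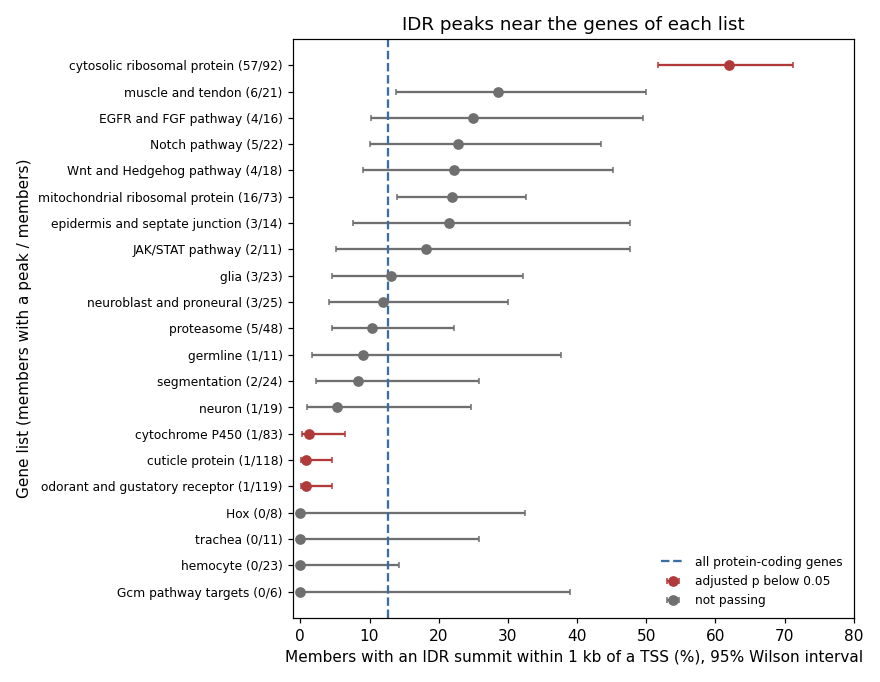
Share of each list's protein-coding genes (%) with an IDR summit within 1 kb of a TSS, with 95% Wilson intervals; the dashed line is the share over all protein-coding genes, and red marks lists that passed. Cytosolic ribosomal proteins lie at 62.0%, against 12.6% of all genes, and the Gcm pathway and hemocyte lists at 0.

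The remaining lists did not pass the test, though some passed in other settings. With summits anywhere in the gene body or 1 kb upstream, muscle and tendon (odds ratio 4.39), EGFR and FGF (5.85) and epidermis and septate junction genes (4.38) passed. Long genes hold more summits by chance in that setting, which was not matched on gene length. Within 1 kb of a TSS, these lists were set against random lists matched on gene length, without or with the number of TSSs. They gave 1.23 to 1.48, 1.23 to 1.28 and 1.01 to 1.13 times the mean, in the same order, and did not pass. Notch genes passed within 5 kb of a TSS (5.07), a distance at which neighbouring genes can share a summit. EGFR and FGF genes passed without replicate 2 (5.37). Muscle and tendon genes with a peak numbered 6 of 21 (odds ratio 2.77, Fisher's exact test, adjusted p = 0.14), among them sls (signal 114), tin (signal 88.8) and Mef2 (signal 79.8). Mitochondrial ribosomal proteins numbered 16 of 73 (odds ratio 1.95, adjusted p = 0.13 by the same exact test), led by mRpS23 (signal 417), mRpS10 (signal 384) and mRpL41 (signal 380). Against random lists matched on gene length, this list passed (2.99 times the mean, permutation test, adjusted p = 0.0014, and 0.0014 to 0.80 over 10 alternatives), as it did within 5 kb of a TSS (odds ratio 2.27) and against lists matched also on the number of TSSs, a setting added later (2.98 times the mean). Developmental lists gave 5 of 22 for Notch, with numb (signal 181), E(spl)m7-HLH (signal 76.4) and kuz (signal 69.4), 4 of 16 for EGFR and FGF, with spi (signal 153), aop (signal 96.8) and Ras85D (signal 64.3), and 4 of 18 for Wnt and Hedgehog, with nkd (signal 90.9), Wnt6 (signal 80.6) and arr (signal 73.6). Counts were 3 of 25 for neuroblast and proneural genes, with brat (signal 166), CycE (signal 70.3) and insc (signal 60.5), 3 of 14 for epidermis and septate junction, with Atpalpha (signal 84.6), crb (signal 63.6) and yki (signal 61.6), 2 of 24 for segmentation, with nkd and bcd (signal 69.1), and 2 of 11 for JAK/STAT, with Stat92E (signal 99.1) and Socs36E (signal 64.2). Neuron genes gave 1 of 19, elav (X:523338-523642, signal 243), germline genes 1 of 11, bgcn (signal 149), and proteasome genes 5 of 48, with Rpn5 (signal 87.0), Rpn3 (signal 80.03) and Rpn6 (signal 61.7). Hox (0 of 8) and trachea (0 of 11) genes had no IDR summit within 1 kb of a TSS, which allows shares of up to 37.5% and 27.3% (Wilson upper bounds 32.4% and 25.9%). Each replicate's own strongest regions reached 1 trachea gene (odds ratios 0.68 and 0.69). With gene bodies or 1 kb upstream counted, 1 Hox gene, Antp, and 1 trachea gene, rib, had an IDR summit. Leaving out 1 library moved several of these odds ratios by more than 1.5 times. Without replicate 2 they were 1.62 for muscle and tendon, 1.15 for epidermis and septate junction (1.89 with the IDR peaks), 3.22 for Notch (2.04) and 1.53 for germline genes (0.69). Without replicate 3 they were 0 for JAK/STAT (1.54), where the strongest regions of replicate 2 reached 0 genes and those of replicate 3 reached 2, 0.80 for neuron (0.38) and 0.45 for proteasome genes (0.80). Neuroblast and proneural genes gave 0.59 and 0.60 (0.94).

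Around the tagged gene itself, gcm2 (2L:9608562-9612706, plus strand) held no IDR summit, and 7 pooled candidate summits lay inside it. Its promoter candidate (2L:9608104-9608567, signal 47.3) had a GCM octamer within 100 bp. The nearest IDR summit lay 722 bp beyond the gene (2L:9613196-9613659, signal 88.5), at Trx2. Within 50 kb of gcm2 there were 12 IDR peaks and 63 pooled candidates, and the strongest peak (2L:9567371-9567661, signal 443, rank 17) lay between jp and brwl. The paralog gcm (2L:9579498-9581745, minus strand) held no summit of the pooled candidates, and the nearest IDR summit lay 2647 bp away.

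**Figure D4:**
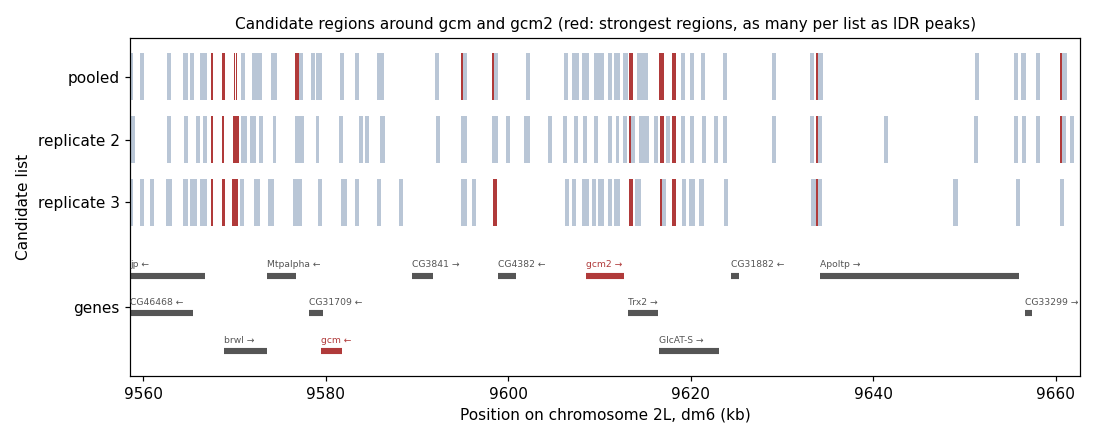
Candidate regions of the pooled list and of each replicate within 50 kb of gcm2 on chromosome 2L (dm6, kb), with protein-coding genes drawn below (gcm and gcm2 in red) and red marking the 2177 strongest regions of each list. Among these, regions lie near jp and brwl and at Trx2 and GlcAT-S, and none lies inside gcm2.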

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

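The settings limited to promoters, to candidates just below the IDR peaks, to genes near a candidate or to genes on the listed chromosomes, and random lists matched also on the number of TSSs, were chosen after seeing the data. In the 7 to 10 alternatives of each, promoters (odds ratio 1.24 to 8.74), coding exons (0.0120 to 0.123) and cytosolic ribosomal genes (odds ratio 7.06 to 12.7, and 6.82 and 3.91 times the mean of matched random lists) kept their direction and their side of the threshold, and the Gcm pathway, glia and hemocyte lists never passed. Causes of the changes below were not tested. Shared regions were 51.4% within 50 bp, 69.6% within 250 bp, 70.5% for any overlap, 66.1% for reciprocal overlap, 70.8% with fewer regions and 56.0% with more.

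The GCM odds ratio lost its call at 50 bp (0.50), at 250 bp (0.81), against positions 1 kb away (0.58), matched on GC (0.77), at promoters only (0.75) and against candidates just below the IDR peaks (0.71), and leaving out a replicate gave 0.43 to 0.66, with the call lost without replicate 3. Over 1000 random GC matchings its median was 0.76, from 0.61 to 0.98. DRE lost its call over 500 bp from a TSS (1.01) and against the candidates just below (1.06). Among motifs that passed in the main or the alternative setting, some directions reversed. These were GAF (0.96 at 50 bp, 0.93 against the candidates just below), M1BP (0.66 over 500 bp from a TSS, 0.65 against the candidates just below), homeodomain (0.89 matched on GC) and the E-box (1.26 against positions 1 kb away and 1.42 matched on GC). Motifs passing went from 8 to 3 at 50 bp, 4 over 500 bp from a TSS, 2 at promoters and 0 against the candidates just below, where annotation classes passing went from 6 to 2.

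With the stronger IDR peaks alone, chromosome 4 lost its call (odds ratio 0.71), X gained one (1.20) and 3 chromosomes passed in place of 1. Without a replicate, 0 to 2 passed, with odds ratios of 0.37 to 0.42 for chromosome 4 and 1.07 to 1.18 for X. Lists passing went from 4 to 7 with gene bodies and to 1 with only genes near a candidate. Over all results, 38 of 49 annotation values, 18 of 24 chromosome values, 83 of 120 motif values and 198 of 210 list values kept their side of the threshold. Those that passed also kept their direction. Values that passed in neither setting were counted as kept even where they crossed 1, such as JAK/STAT genes without replicate 3 (1.54 to 0). The dm3 count of 2459 peaks lay within 1.5 times the dm6 count. Read depth is unknown, and lists of few genes limit the gene counts.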

Other observations

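The octamer and gene type tests, the measures at the gcm2 locus, the ratio of centre to flank, the settings at promoters and stratified on promoters, the genes near a candidate as background and the use of other settings and lists to test an explanation were chosen after the results had been seen. The gene lists, the 500 bp distance and matching on GC content had been fixed earlier, but not the GC estimator. Octamers more frequent at IDR peaks than at weak candidates were ranked on chromosomes 2L and 2R and counted on the others. All 20 top octamers also passed there (Fisher's exact test, two-sided, adjusted within the 20). Most were rich in A and T, such as ATTTAAAA (9.50% of IDR peaks against 4.55%, odds ratio 2.20), which goes with the lower GC content of these windows. An octamer with 5 G or C bases, CACAGTGG, had the highest odds ratio of the 20 (6.68% against 1.53%, odds ratio 4.61, Fisher's exact test, adjusted p = 2.4e-25), and ACAGTGGG, which overlaps it, gave 4.53% against 1.28%. TATCGATA, the DRE, ranked 20. Octamers of the GCM consensus ranked from 3921 to 29504 of 31467. By gene type, TSSs of noncoding RNA genes lay within 500 bp of 4.87% of IDR summits and 2.96% of weak ones (odds ratio 1.68, Fisher's exact test, adjusted p = 1.6e-05). Those of protein-coding genes lay near 54.8% and 27.6% (odds ratio 3.17), while tRNA, snoRNA and snRNA genes did not pass. Each type was tested alone, and a summit near both kinds of TSS counted in both. Any annotated TSS lay within 500 bp of 57.7% of IDR summits and 30.3% of weak ones, little above the protein-coding shares of 54.8% and 27.6%. Summits near only a TSS of another gene type were thus about as frequent in both sets, a comparison that was not tested. These shares argue against a noncoding difference of that size apart from the one at protein-coding promoters.

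Candidate regions were dense over gcm2. In a 24145 bp window around the gene they covered 9300 bp, against a median of 3387 bp around other protein-coding genes, at percentile 99.7, and the window of gcm lay at percentile 95.001. Whether extra copies of gcm2 sequence in the transgenic line contribute was not tested. Binding of the tagged protein at GCM sites of its own locus stays open: 2 of 23 candidates there had a match (odds ratio 6.11, interval 0.693 to 25.1), too few to tell. An untagged or mock library was not analysed here.

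The GCM octamer was rarer at IDR peaks than at weak candidates, a call kept in only 3 of 10 alternative settings and lost without replicate 3 (odds ratio 0.66). Permuted consensuses were also mostly rarer at IDR peaks, with a median IDR to weak ratio of 0.68. Of the 100, 77 had a ratio at least as high as the 0.49 of GCM, so the rarity was not particular to its sequence. A larger share of promoters is argued against as the whole cause: over 500 bp from a TSS the odds ratio was 0.31 (interval 0.1001 to 0.737, 5 IDR matches), and stratified on promoters it was 0.52 (interval 0.283 to 0.799), although at promoters alone it was 0.75 (interval 0.372 to 1.36) and did not pass. Lower GC content may contribute: matched on GC the odds ratio was 0.77 (interval 0.425 to 1.18), nearer 1 than the unmatched 0.49. All 1000 random matchings on GC gave values above 0.49, the lowest 0.61, but each kept the same 17 IDR matches. Their spread therefore leaves out the counting error of those matches and adds no independent evidence. How much of the difference goes with GC content stays open, since the interval holds both 1 and 0.49. Among weak candidates the octamer was 1.46 times denser within 100 bp of the summit than at 400 to 990 bp, and 0 of 100 permuted consensuses reached that ratio (median 1.11, highest 1.37). Binding of the tagged protein at GCM sites among weak candidates is thus a hypothesis that fits that count of 0, found and tested on the same data. At IDR peaks the octamer was no denser near the summit: 45.9 per Mb within 50 bp (10 matches) and 41.3 at 50 to 100 bp. Farther out it gave 50.5 at 400 to 700 bp and 46.7 at 700 to 990 bp. Among pooled candidates the GCM share did not rise with signal. It was 0.972% in the rank group just below the IDR peaks and 1.53% in the weakest group. Neither result goes with that hypothesis, which stays open.

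Cytosolic ribosomal protein genes carried IDR peaks far more often than other genes (odds ratio 11.6, interval 7.45 to 18.3). Signal at the promoters of broadly active genes in general stays open. The proteasome list, 5 of 48 genes, gave 0.80 (interval 0.248 to 2.03, and 0.45 without replicate 3), which holds 1 but lies below 7.45. This counts against signal of equal strength at the genes of this list only. The list was drawn up by symbol pattern, and whether all its members are broadly active was not checked. Of its 48 genes, 34 had any pooled candidate within 1 kb of a TSS. The bound by which this list was judged was changed after its value was seen: by the first, an upper bound below 7.45, the explanation was argued against as the whole cause, and by the second, an upper bound below 1, it is not. The mitochondrial ribosomal list gave 1.95 (unadjusted interval 1.04 to 3.45), did not pass in the test over 21 lists, without replicate 3 (1.63), without replicate 2 (1.79) or against genes with a candidate near a TSS (1.24), and passed within 5 kb (2.27) and against length-matched lists (2.99 times the mean). No mock or untagged library was analysed here, so such signal and binding of the tagged protein cannot be told apart; a link to very high transcription and biological explanations of this pattern were not tested.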
